A study of Homo sapiens with 6 samples.

How the data were processed

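RNA was measured in 6 libraries of K562 cells, 3 biological replicates labelled WT and 3 labelled ACK KO. Per the labels, the cells were grown in RPMI medium with 10% fetal bovine serum and collected beside material for CUT&RUN, and stranded polyadenylated RNA libraries with unique molecular identifiers were made from 500 ng of RNA with an integrity number of 10 for each. The processing notes of the authors list FastQC 0.11.7, SAMtools, STAR 2.7.2b, Salmon 1.1.0, DESeq2 1.26.0 and R 3.6.1 with the GRCh38 genome, without the role or order of each. The annotation release and the counting settings are not given in the sources used here.

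The deposited values are a signal, gene-level normalised counts that the authors obtained by dividing estimated read counts by a normalisation factor, not log transformed. They are not whole reads, and whole reads could not be recovered, since 13.5% to 54.0% of the low values of a library lay on a common step. The file holds 19498 genes, the lowest mean of a gene being 3.38, so a filter on low means had been applied, and 1086 genes have a value of 0 in some library. Gene symbols came from a name table that holds 19392 of the identifiers, and positions and biotypes from GENCODE 29, which holds 19112, of which 13771 are protein-coding. The order of the genes in the file had a Spearman correlation of 0.881 with the p-values of the unblocked test below and of 0.989 with those of the blocked test. Values per library sum to 46.7 M, 53.3 M and 50.3 M in WT and to 43.5 M, 49.5 M and 47.3 M in the libraries labelled ACK KO. Read depth is unknown, so the precision of a value is given by the spread between libraries alone.

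Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with moderated t tests and an intensity trend, for 16658 genes with a value of 10 or more in at least 3 of 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold, with at least 2-fold as a second threshold. Log2 differences are KO-labelled minus WT, means and SD are of normalised values with n = 3 per group, and folds are 2 to the power of the size of the fitted log2 difference. TNK2 was also tested by an exact permutation of the 6 libraries. The 25 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over the 25 lists. With an estimated correlation camera has only the residual degrees of freedom that 6 libraries leave. It has little power here, and a list that fails it may still have moved. The preset correlation makes p-values too small where the members of a list vary together more strongly than 0.01. Library structure was described by principal components and Pearson correlations.

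The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes TNK2, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of 100 or more in the higher group, no overlap between groups and a symbol that is not a clone or locus name, and up to 4 members of each list by smallest p, with the most abundant members for lists of other cell types or RNA quality. Some genes that the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen, and the text says so where it names them. The lists hold STAT5 targets, JAK-STAT components, erythroid, megakaryocyte, monocyte and granulocyte, stem and progenitor, ERK output, Cdc42 effector, ACK partner, clathrin and endocytosis, actin and adhesion, interferon-stimulated, MHC, BCL2 family, cell cycle, ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, stress response, 3q29, lymphoid, epithelial and fibroblast, mitochondrially encoded, histone and heat shock genes.

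The deviations of each library from its group mean were compared between WT and KO-labelled libraries of the same replicate number. Their correlations across genes were 0.699, 0.521 and 0.342 for replicates 1, 2 and 3, each above the limit of 0.1 set in advance. Unlike numbers gave 0.281 (WT 2 with ACK KO 3) and 0.257 (WT 3 with ACK KO 2), also above that limit. Numbers 2 and 3 are therefore less clearly told apart than number 1. The 3 deviations of a genotype sum to 0, so the values of numbers 2 and 3 follow in part from that of number 1. By the limit, the numbers were treated as pairs in a second fit with the replicate number as a block, and blocked values stand beside results whose call or count they change. The labels do not say what the numbers stand for.

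The tests were checked on simulated data with the spread of these libraries. Without a shared replicate effect the unblocked test found 21% of 100 genes changed by a log2 of 1 and 54% of 100 changed by a log2 of 2, with 1 false call among 16658 genes. With a shared effect it found 9% and 49% with 0 false calls, and the blocked test found 46% and 68% with 2 false calls. The shared effect was taken from the blocked fit of these data, so the gain of the blocked test was built in. Of 200 random lists of 30 unchanged genes camera passed 2.5% at an unadjusted p of 0.05. The simulated genes varied independently, so this share does not cover lists whose members vary together.

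Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a filter on a mean of 50, trimmed mean of M-values scaling, quantile normalisation, limma without the trend, voom weights, the block, and leaving out each library in turn. Leaving out both replicate 1 libraries was added after the data were seen. Tests on whole counts were not run, because the values are not whole reads.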

Results

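K562 is a human cell line from a chronic myeloid leukaemia that carries the BCR::ABL1 fusion kinase and keeps erythroid and megakaryocytic features. Polyadenylated RNA from K562 cells labelled WT and from K562 cells labelled ACK KO was sequenced in 3 biological replicates per genotype, 6 libraries in all. ACK, a non-receptor tyrosine kinase that binds the small GTPase Cdc42, is the product of TNK2. The title of the series places the work around ACK and the transcription driven by STAT5, a transcription factor that is constantly active downstream of BCR::ABL1. The values are normalised read counts for 19498 genes, whose sums per library ranged from 43.5 M to 53.3 M. The number of reads behind each library is unknown, so no counting error is attached to single values, and errors below are the spread between 3 libraries. The labels do not say whether the replicates came from separate clones or cultures, and the p-values measure only the spread between these libraries.

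TNK2 was measured first. The gene (ENSG00000061938.18) lies on the minus strand of chromosome 3, from 195863364 to 195911945 in GRCh38. Its normalised values were 829.7, 613 and 642 in WT replicates 1 to 3 and 741, 506 and 598 in the libraries labelled ACK KO. The group means were 695 ± 118 and 615 ± 119 (SD, n = 3 each), a log2 difference of -0.18 with a standard error of 0.21 and a 95% interval from -0.68 to 0.32. An exact two-sided permutation test gave p = 0.4, where 0.1 is the smallest p that 3 against 3 libraries can give. That test ignored the replicate numbers. In each number the KO-labelled value was the lower, and with the block the standard error was 0.10 and the adjusted p 0.207 (limma). The amount of TNK2 mRNA therefore does not check the genotype labels, since a small deletion or insertion in the coding sequence can leave mRNA in place, and the position of the edit is not given in the sources used here. The libraries are called KO-labelled below for this reason. The labels name 1 cell line per genotype, so a difference between genotypes and a difference between lines or clones cannot be told apart in any value that follows.

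The 6 libraries separated by genotype label first and by replicate number second. The first principal component held 59.7% of the variance and placed the 3 WT libraries opposite the 3 KO-labelled libraries. The second held 26.8% and placed replicate 1 of both genotypes apart from replicates 2 and 3. Pearson correlations of log2 values across genes were 0.958 to 0.987 within WT, 0.968 to 0.988 within the KO-labelled group and 0.908 to 0.938 between the groups.

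**Figure D1:**
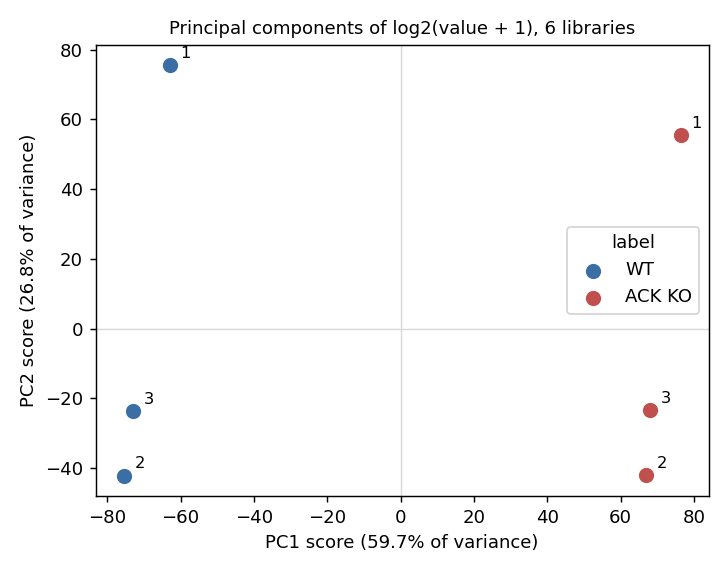
Principal component scores of the 6 libraries, computed on log2(value + 1) of the 16658 tested genes; each point is 1 library, coloured by genotype label and numbered by replicate. The horizontal axis (59.7% of variance) parts the genotype labels and the vertical axis (26.8%) parts replicate 1 of both from replicates 2 and 3.

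The deepest fall among the named genes of the KO-labelled libraries was that of PTPRC, which encodes the leukocyte surface phosphatase CD45. It fell from 15492 ± 2538 to 17.9 ± 6.52 (SD, n = 3 each), 854-fold on the log2(value + 1) scale. ARHGDIB fell 411-fold from 3298 ± 518 to 7.203 ± 2.41. The receptor phosphatase gene PTPRB fell 319-fold, the Rac GTPase-activating protein gene ARHGAP15 fell 454-fold, and TGFBR2, which encodes a TGF-beta receptor, fell 276-fold. The adaptor gene FYB1 fell from 773 ± 368 to 0.374 ± 0.648, the gene of the tyrosine kinase SYK from 1032 ± 260.4 to 7.28 ± 11.5, CCDC141 from 2645 ± 1397 to 6.09 ± 5.24, and CYB5A, which encodes cytochrome b5, from 467 ± 83.6 to 0.205 ± 0.355. SYK had KO-labelled values of 0.591, 20.6 and 0.63, so the size of its fall also depends on the pseudocount. Its log2 difference was -8.05, and -7.41, -9.30 and -7.43 without KO-labelled replicates 1, 2 and 3 in turn. That of CCDC141 was -8.78, and -8.04 and -9.37 without KO-labelled replicates 1 and 2. With a pseudocount of 5 in place of 1 the log2 differences of ARHGDIB, ARHGAP15 and TGFBR2 were -8.09, -8.04 and -7.38 against -8.68, -8.83 and -8.11. ZNF594, LRRK2 and the progesterone receptor gene PGR had WT means of 285, 287 and 266 and were listed at 0 in the 3 KO-labelled libraries. FYB1 lies on chromosome 5, whose 693 tested genes had a median log2 difference of -0.62, and CYB5A in a segment of chromosome 18, 46.1 to 74.5 Mb, with a median of 0.54. These 12 falls had adjusted p-values from 3.78e-05 to 0.00404 (limma, Benjamini-Hochberg).

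The largest rises were of genes near silence in WT. SPARC, which encodes a secreted matrix glycoprotein, rose from 13.7 ± 4.46 to 5947 ± 1460.3 (SD, n = 3 each), 411-fold, and lies on chromosome 5 like FYB1. RAB13, a small GTPase gene, rose 252-fold from 6.77 to 1776, EPB41L3, which encodes a membrane-cytoskeleton linker, rose 227-fold to 1363, SCML1 rose from 2.04 ± 2.44 to 724 ± 49.1 and ANKRD62 from 0.678 ± 0.596 to 359 ± 38.3. SCML1 had WT values of 4.74, 1.38 and 0, so the size of its rise also depends on the pseudocount. Its log2 difference was 8.24, and 8.88 and 7.62 without WT replicates 1 and 3. With a pseudocount of 5 the log2 differences of RAB13 and EPB41L3 were 7.30 and 7.08 against 7.98 and 7.83. A further 7 genes were listed at 0 in the 3 WT libraries and had KO-labelled means of 975 (SNRPN, an imprinted gene), 547 (SEC14L6), 451 (PCDH10, a protocadherin gene), 269 (C12orf40), 266 (ZC3HAV1L), 250.2 (LHFPL3-AS2) and 234 (PDK4, a pyruvate dehydrogenase kinase gene). ZC3HAV1L, LHFPL3-AS2 and PDK4 lie on chromosome 7, whose 834 tested genes had a median log2 difference of 0.39. LHFPL3-AS2 is an antisense transcript, and since the counting settings are not given in the sources used here its value is uncertain, as is that of SNRPN, which shares exons with SNURF. The adjusted p-values of these 12 genes ran from 3.78e-05 to 5.46e-04 (limma). The calls of the 24 genes held in each fit that left out 1 library, with SYK closest to the threshold at 0.0245 without WT replicate 3.

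In total 1721 of 16658 tested genes (10.3%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 894 higher and 827 lower in the KO-labelled libraries. Of these, 1217 differed at least 2-fold, 647 higher and 570 lower. Every KO-labelled library lay above or below every WT library for 4996 tested genes (29.99%), where chance gives 10%. A mean of 100 or more in the KO-labelled group with every WT library under 10 was found for 39 genes, 25 of them protein-coding. The reverse was found for 50 genes, 38 of them protein-coding, out of 12510 genes that reached a mean of 100 in either group. With the replicate number as a block 6612 genes passed, 3275 higher and 3337 lower, of which 2164 at least 2-fold, and the 1721 genes were all among them. Without WT replicates 1, 2 and 3 in turn the count was 2183, 921 and 748. Without KO-labelled replicates 1, 2 and 3 in turn it was 1214, 929 and 726. The count at least 2-fold was 1494 without WT replicate 1, 716 without WT replicate 3 and 696 without KO-labelled replicate 3. Leaving out both replicate 1 libraries, a choice made after their separate position was seen, gave 4731 genes, 1899 of them at least 2-fold.

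**Figure D2:**
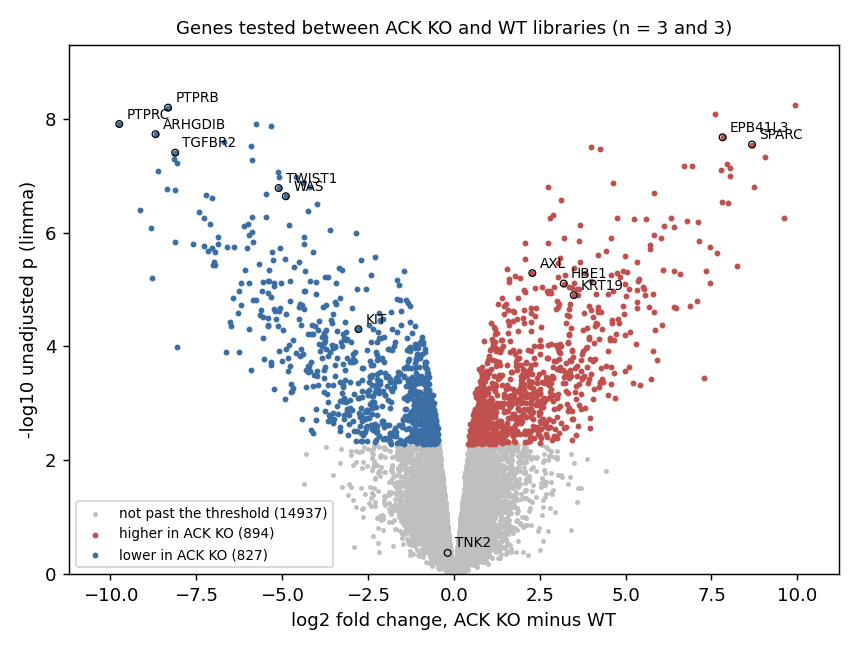
Log2 difference between KO-labelled and WT libraries (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 16658 genes; red points (894) and blue points (827) passed an adjusted p of 0.05 and grey points did not. PTPRC, PTPRB, ARHGDIB and TGFBR2 lie at the left edge, SPARC and EPB41L3 at the right, and TNK2 near 0; fitted values of genes listed at 0 in a group depend on the pseudocount.

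Neighbouring genes shifted together on some chromosomes, which were singled out after their values were seen. Genes on chromosome 5 had a median log2 difference of -0.62 (693 tested genes, 87.3% below 0), those on chromosome 20 of 0.54 (393 genes, 90.1% above 0) and those on chromosome 7 of 0.39 (834 genes, 84.3% above 0). The medians of the 3 replicate pairs were -0.64, -0.64 and -0.63 on chromosome 5, 0.57, 0.51 and 0.55 on chromosome 20, and 0.41, 0.37 and 0.38 on chromosome 7. Shifted windows of neighbouring genes covered nearly all of chromosomes 5 and 20 and, on chromosome 7, 8 segments with 645 of its genes. Whole-chromosome medians elsewhere ran from -0.10 to 0.18, but 13 segments of other chromosomes, with 655 genes, were shifted too, among them X from 48.5 to 49.3 Mb (median -0.87) and from 101.4 to 103.6 Mb (0.78), and segments of chromosomes 18 (0.54), 1 (0.52), 14 (0.50) and 15 (0.50). Of the changed genes with a position, 438 lie on these 3 chromosomes, 390 of them with the sign of their chromosome, and 1253 lie elsewhere, 164 of these in shifted windows.

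**Figure D3:**
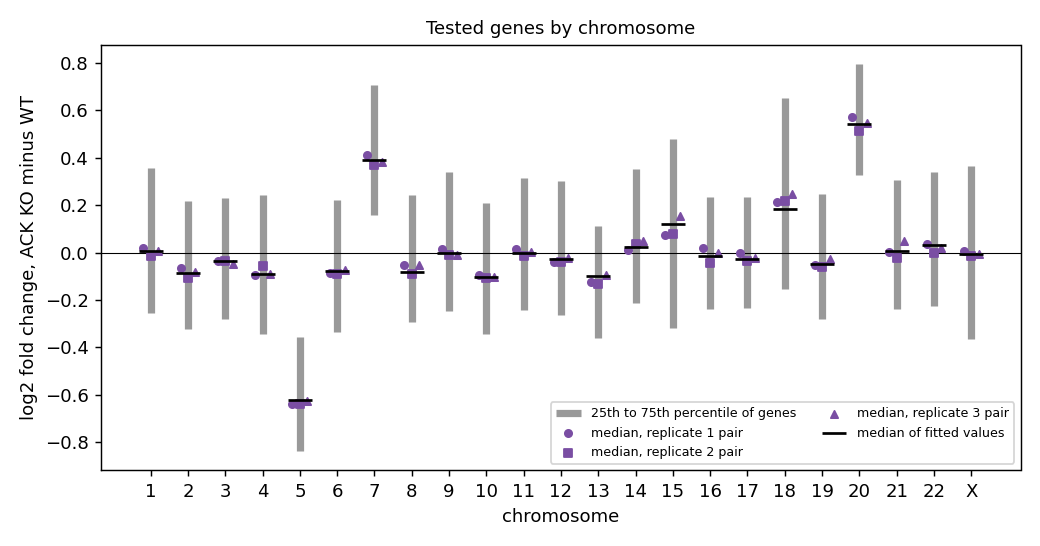
Log2 difference between KO-labelled and WT libraries for the tested genes of each chromosome; black bars are medians, grey bars the 25th to 75th percentile, and purple symbols the medians of the 3 replicate pairs. Chromosome 5 lies below 0 (median -0.62), and chromosomes 7 (0.39) and 20 (0.54) lie above it in each pair.

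STAT5 target genes were the first of 25 lists fixed before the data were examined, and every list test below was adjusted over the 25. Of 24 members tested, 1 rose, 3 fell and 20 did not pass, with 1 up and 5 down when adjusted over the list alone and 4 up and 11 down with the block. LTB, which encodes lymphotoxin beta, fell from 111 ± 84.7 to 3.001 ± 3.03 (SD, n = 3 each), and PIM2, a serine/threonine kinase gene, fell 1.87-fold from 10976 ± 395 to 5943 ± 1197. The log2 difference of LTB was -4.92, and -4.33 without WT replicate 3, -4.12 without KO-labelled replicate 2 and -5.53 without KO-labelled replicate 3. CCND3, the cyclin D3 gene, fell 1.44-fold. CDKN1A, which encodes the cell cycle inhibitor p21, rose 4.23-fold from 189.9 ± 64.02 to 875 ± 494. Their adjusted p-values (limma) were 0.0154, 0.02003, 0.0486 and 0.0358. None of the 4 calls held in every fit without 1 library, where no block was used. Without WT replicate 3 the adjusted p (limma) was 0.0658 for LTB, 0.0839 for PIM2 and 0.171 for CCND3, and without KO-labelled replicate 3 it was 0.136 for CDKN1A. On all 6 libraries with the block the adjusted p (limma) was 7.19e-04 for LTB, 8.09e-04 for PIM2, 0.00274 for CCND3 and 2.38e-04 for CDKN1A. PIM2 lies in a segment of the X chromosome, 48.5 to 49.3 Mb, whose 36 tested genes had a median log2 difference of -0.87. The list as a whole did not pass camera, a test of the list against the other genes, with an adjusted p of 0.271 and 0.297 with the block (limma).

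Further STAT5 genes were chosen after their values were seen. CISH, a direct STAT5 target that feeds back on the pathway, had a log2 difference of -0.07 (SE 0.22), an adjusted p (limma) of 0.887 and means of 5517 ± 1462 in WT and 5174 ± 815 in KO-labelled libraries (SD, n = 3 each). Without WT replicate 1 its log2 difference was 0.13 and without KO-labelled replicate 1 it was 0.03. PIM1 had values of 69788, 26467 and 26886 in WT and 22549, 16402 and 14113 in KO-labelled libraries, an adjusted p of 0.157 and 0.00208 with the block (limma). STAT5A and STAT5B had log2 differences of 0.20 (SE 0.14) and 0.25 (SE 0.29), with adjusted p-values (limma) of 0.458 and 0.6702. The blocked adjusted p for STAT5A was 0.0449.

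Among 26 components of the JAK-STAT pathway 1 rose, 4 fell and 21 did not pass, with 1 up and 4 down over the list alone and 5 up and 7 down with the block. PTPN6, which encodes the phosphatase SHP-1, fell from 98.5 ± 11.97 to 9.11 ± 5.89 (SD, n = 3 each), and CSF2RB, the shared beta chain of the GM-CSF receptor family, fell from 18.2 to 1.68. Their log2 differences were -3.53, and -2.90 without KO-labelled replicate 2, and -3.05, and -2.44 without KO-labelled replicate 1. STAT4 fell 2.51-fold and STAT3 1.74-fold, the latter from 16452 ± 2757 to 9432 ± 1190.3. JAK1 rose 1.72-fold, and it lies in a segment of chromosome 1 from 58.4 to 99.97 Mb whose 140 tested genes had a median log2 difference of 0.52. The 5 adjusted p-values (limma) were 0.0108, 0.0233, 0.00717, 0.0271 and 0.00789. Without 1 library the adjusted p (limma) reached 0.0574 for PTPN6 (without WT replicate 3), 0.0863 for CSF2RB (without WT replicate 2), 0.124 for STAT3 (without KO-labelled replicate 3) and 0.0545 for JAK1 (without KO-labelled replicate 3). The camera adjusted p was 0.654.

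Erythroid genes included the embryonic globin gene HBE1, which rose 9.19-fold from 1315 ± 256 to 12385 ± 4308 (SD, n = 3 each; adjusted p 7.84e-04, limma). FECH, which encodes the enzyme that inserts iron to form haem, rose 2.64-fold (adjusted p 0.00114, limma). FECH lies in the chromosome 18 segment named above, which holds 71 tested genes. CA2, a carbonic anhydrase gene at low values, fell from 17.5 to 2.65, with an adjusted p (limma) of 0.0144 and of 0.0606 without WT replicate 2. Of 32 members 6 rose, 1 fell and 25 did not pass, with 8 up and 2 down over the list alone and 12 up and 6 down with the block. As a list the members had a camera adjusted p of 0.271. Globin genes of near-identical sequence, HBA1 with HBA2 and HBG1 with HBG2, are uncertain because reads can be split between the copies.

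Megakaryocyte genes moved in both directions. ITGA2B, which encodes platelet integrin alpha IIb, fell 7.62-fold from 1353 ± 327 to 188 ± 82.8 (SD, n = 3 each), while GP1BB, a subunit of the von Willebrand factor receptor, rose 3.05-fold, NRGN rose 3.63-fold and the tetraspanin gene CD9 rose 3.23-fold. Their adjusted p-values (limma) were 0.00601, 7.29e-04, 0.00665 and 0.00796. Read-through transcripts join GP1BB to its neighbour SEPTIN5, so its value is uncertain. The remaining calls were a rise of PDGFB from 5.49 to 38.8 and falls of RAB27B from 481 to 13.1 and of ANGPT1 from 5065 to 2621, chosen after their values were seen. RAB27B lies in the chromosome 18 segment of FECH, and its log2 difference was -5.24, and -4.63 without WT replicate 1 and -4.35 without KO-labelled replicate 2. Leaving out KO-labelled replicate 3 took PDGFB to an adjusted p of 0.15, and leaving out WT replicate 3 took ANGPT1 to 0.151 (limma). Of 15 members 4 rose, 3 fell and 8 did not pass, with 5 up and 4 down over the list alone and 5 up and 5 down with the block; camera gave an adjusted p of 0.792.

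In the monocyte and granulocyte list 3 of 11 members fell and 8 did not pass. The Fc receptor gene FCGR2A fell 5.01-fold from 4586 ± 2597 to 876 ± 355 (SD, n = 3 each), CD33, a myeloid sialic acid receptor gene, fell 1.77-fold and CD68, a macrophage lysosomal gene, fell 2.33-fold. Their adjusted p-values (limma) were 0.0192, 0.0161 and 0.0283, and they reached 0.0826 (without KO-labelled replicate 3), 0.0737 (without WT replicate 2) and 0.119 (without WT replicate 3). SPI1, which encodes the myeloid factor PU.1, had means of 844 ± 236 and 333 ± 259.8, a log2 difference of -1.57, and -2.16 without KO-labelled replicate 1, an adjusted p of 0.113 and 0.00231 with the block (limma). CEBPB, an abundant member, had means of 1135 ± 560.1 and 2282 ± 1113, an adjusted p of 0.209 and 1.55e-04 with the block, and lies on chromosome 20. The list had 1 up and 4 down over the list alone, 3 up and 5 down with the block, and a camera adjusted p of 0.571. Stem and progenitor genes had 2 falls and 9 members that did not pass among 11, with 1 up and 3 down with the block. KIT, the stem cell factor receptor gene, fell 6.85-fold from 1850.3 ± 789.7 to 257 ± 46.2 with an adjusted p of 0.00255, and LYL1, a haematopoietic transcription factor gene, fell 1.61-fold with an adjusted p of 0.038 that became 0.159 without KO-labelled replicate 3 (limma). MYB and TAL1 had log2 differences of -0.38 (SE 0.14) and 0.19 (SE 0.13) and adjusted p-values (limma) of 0.1696 and 0.427, with 0.00616 for MYB with the block. Camera gave the list an adjusted p of 0.391.

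ACK is an effector of Cdc42, and the list of Cdc42 and its effectors had 6 rises, 3 falls and 25 members that did not pass among 34, with 8 up and 5 down over the list alone and 10 up and 8 down with the block. WAS, which encodes the blood-cell actin nucleation factor WASP, fell 29.6-fold from 737 ± 48.4 to 24.2 ± 4.55 (SD, n = 3 each), in the same X chromosome segment as PIM2. FMNL2, a formin gene, fell 5.803-fold and CDC42EP4, chosen after its values were seen, fell 1.54-fold. DIAPH2, another formin gene, rose from 5.03 to 60.1, and CDC42BPB, a kinase gene, rose 1.77-fold. By limma the adjusted p-values were 9.60e-05, 0.00434, 0.0216, 0.00179 and 0.0169. Without KO-labelled replicate 3 they were 0.119 for CDC42EP4 and 0.0915 for CDC42BPB. CDC42BPB lies on chromosome 14 in a segment from 92.1 to 103.3 Mb with a median log2 difference of 0.50. Camera gave an adjusted p of 0.628.

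AXL, a receptor tyrosine kinase gene in the list of ACK binding partners and substrates, rose 4.88-fold from 195 ± 18.9 to 959 ± 113 (SD, n = 3 each; adjusted p 6.40e-04, limma). STAT3, described above, was the fall in that list, and 26 of 28 members did not pass; 7 rose and 5 fell with the block. NEDD4L, a ubiquitin ligase gene, and SNX9, a sorting nexin gene, had adjusted p-values (limma) of 0.05596 and 0.0633, and of 8.22e-05 and 0.00229 with the block. Their means were 1566 ± 485 and 4779.8 ± 182 in WT and 3613 ± 1269 and 6276 ± 168 in KO-labelled libraries. NEDD4L lies in the chromosome 18 segment of FECH. In the clathrin and endocytosis list SNX33 rose 1.78-fold, the clathrin assembly gene PICALM fell 1.504-fold and FCHO1 fell 2.06-fold, with adjusted p-values (limma) of 0.0274, 0.0229 and 0.0132, and 27 of 30 did not pass. These 3 calls were lost without 1 library, with adjusted p up to 0.116 (SNX33, without WT replicate 3), 0.122 (PICALM, without KO-labelled replicate 3) and 0.0618 (FCHO1, without WT replicate 3). With the block 5 rose and 7 fell. SNX33 lies on chromosome 15 in a segment from 67.5 to 78.1 Mb with a median log2 difference of 0.42. Camera gave adjusted p-values of 0.734 and 0.734.

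Actin cytoskeleton and adhesion genes included 2 rises, 6 falls and 23 members that did not pass among 31, with 4 up and 8 down over the list alone and 7 up and 14 down with the block. CALD1, the caldesmon gene, rose from 0.292 ± 0.505 to 50.02 ± 8.79 (SD, n = 3 each) and CNN3, a calponin gene, rose 5.91-fold from 112 to 656. CNN2, another calponin gene, fell 3.503-fold from 7121 ± 745 to 2064 ± 467. ITGA4, an integrin gene of leukocytes, fell from 63.2 to 0.442. The adjusted p-values (limma) of the 4 genes ran from 7.66e-04 to 0.00251. CNN3 shares its chromosome 1 segment with JAK1, and CALD1 lies on chromosome 7. The camera adjusted p was 0.271.

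Interferon-stimulated genes had 1 rise, 4 falls and 16 members that did not pass among 21, with 1 up and 4 down over the list alone and 2 up and 8 down with the block. IFITM2 fell 84.1-fold from 2101 ± 272 to 26.5 ± 13.4 (SD, n = 3 each), IFITM3 fell 4.69-fold, the ubiquitin-like gene ISG15 fell 2.28-fold and IFITM1, chosen after its values were seen, fell 1.79-fold from 13528 ± 2191 to 7551 ± 1230.0. The RNA sensor gene RIGI rose 3.101-fold. Limma gave adjusted p-values of 3.30e-04, 0.00493, 0.0244, 0.0293 and 0.0144. Without WT replicate 3 they were 0.121 for ISG15, 0.115 for IFITM1 and 0.07097 for RIGI. The 3 IFITM genes are close in sequence, so their single values are uncertain. As a list the members had a camera adjusted p of 0.271. Among 13 MHC and antigen presentation genes 3 rose, 0 fell and 10 did not pass. HLA-B and HLA-C rose 2.28-fold and 1.92-fold. Their adjusted p-values (limma) were 0.0338 and 0.0475, with 0.1402 for HLA-B without KO-labelled replicate 3 and 0.179 for HLA-C without WT replicate 3. Reads of these polymorphic paralogs can be shared. B2M, the light chain gene, had means of 15399.5 ± 701 and 11858 ± 1595, an adjusted p of 0.139 and 0.0139 with the block (limma). With the block 4 MHC genes rose and 7 fell, and camera gave an adjusted p of 0.845.

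**Figure D4:**
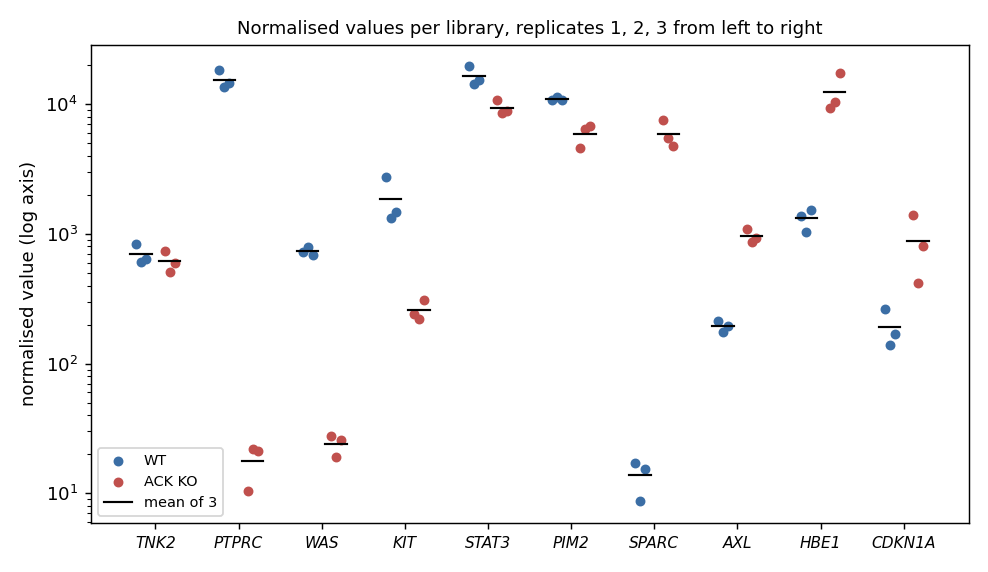
Normalised values per library (log vertical axis) of TNK2 and 9 named genes; blue points are the 3 WT libraries, red points the 3 KO-labelled libraries, and black lines the group means. TNK2 values overlap between the labels, with means of 695 and 615, while the values of the other 9 genes do not overlap.

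In the BCL2 family BOK rose 5.18-fold from 71.3 to 369, PMAIP1, which encodes the BH3-only protein NOXA, rose 2.14-fold, and BNIP3 fell 2.02-fold, with 15 of 18 members not passing. The adjusted p-values (limma) were 0.00176, 0.0229 and 0.0152, and without WT replicate 3 0.105 for PMAIP1 and 0.0691 for BNIP3. PMAIP1 lies in the chromosome 18 segment of FECH. BAD had an adjusted p of 0.1405, and 0.0148 with the block. Of 42 cell cycle genes 2 rose, 1 fell and 39 did not pass, with 1 up and 0 down over the list alone and 6 up and 16 down with the block. CDC25B rose 1.64-fold and E2F1 1.55-fold, both on chromosome 20, whose 393 tested genes had a median log2 difference of 0.54, and the spindle checkpoint gene BUB1B fell 1.62-fold. Adjusted p-values by limma were 0.0118, 0.03996 and 0.0347, and reached 0.07697 (without KO-labelled replicate 3), 0.165 (without WT replicate 3) and 0.141 (without WT replicate 3). KIF20A had an adjusted p of 0.0941, and 0.00465 with the block, and lies on chromosome 5. With the block the BCL2 family had 2 rises and 4 falls. Camera gave adjusted p-values of 0.792 and 0.271.

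ERK pathway output genes had 1 fall among 23, DUSP6, an ERK phosphatase gene that fell from 25.4 to 2.48 at low values (adjusted p 0.0358, and 0.137 without WT replicate 3, limma). Its log2 difference was -3.32, and -2.63 and -4.04 without KO-labelled replicates 1 and 3. Adjusted over the list alone no member passed, while 11 had an unadjusted p under 0.05, 1 passed with voom weights and 2 without the variance trend. With the block 6 rose and 10 fell. CCND1, the cyclin D1 gene, SPRY1 and ETV5 had log2 differences of -1.65, -0.98 and 0.53, adjusted p-values (limma) of 0.0589, 0.0758 and 0.0763, and 2.76e-04, 0.00333 and 0.0112 with the block. Camera gave an adjusted p of 0.664.

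Cholesterol synthesis genes had 4 falls among 25. HMGCS1, the synthase that makes the HMG-CoA used by the pathway, fell 2.71-fold from 19266 ± 3548 to 7159.6 ± 1654 (SD, n = 3 each), EBP fell 2.405-fold and STARD4 fell 2.06-fold. HMGCS1 and STARD4 lie on chromosome 5 and EBP in the X chromosome segment of PIM2. By limma the adjusted p-values were 0.00868, 0.0417 and 0.0212, and without WT replicate 3 they were 0.158 for EBP and 0.0997 for STARD4. With the block 7 members rose and 7 fell. In the glycolysis and hypoxia list PDK3, a pyruvate dehydrogenase kinase gene, fell from 1018 ± 91.5 to 28.4 ± 19.9 (log2 -5.42, and -4.73 without KO-labelled replicate 3), PFKP, a phosphofructokinase gene, fell 2.47-fold, BNIP3 fell as above and P4HA1, a collagen prolyl hydroxylase gene, rose 1.58-fold. The adjusted p-values (limma) were 0.002303, 0.0234 and 0.0136, and without KO-labelled replicate 3 0.0999 for PFKP and 0.0815 for P4HA1. PFKP lies on chromosome 10 in a segment from 0.13 to 5.98 Mb with a median log2 difference of -0.40. Of the list, 26 of 30 members did not pass, and 5 rose and 12 fell with the block. Camera gave adjusted p-values of 0.664 and 0.551.

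Among 30 ribosome biogenesis genes none passed limma without the block, 1 had an unadjusted p under 0.05, and none passed with voom weights or without the variance trend; with the block 1 rose and 13 fell. NPM1, the nucleophosmin gene, had means of 128720.0 ± 35806 and 63534 ± 17236 (SD, n = 3 each) and an adjusted p of 0.0808, and 3.41e-05 with the block (limma). NHP2, UTP15 and WDR12 had adjusted p-values of 0.3098, 0.472 and 0.454, and 9.83e-04, 3.63e-04 and 0.002598 with the block (limma). NPM1, NHP2 and UTP15 lie on chromosome 5. Among 25 genes of the integrated stress and unfolded protein responses none passed without the block, 3 had an unadjusted p under 0.05, and none passed with voom weights or without the variance trend; with the block 13 rose and 1 fell. TRIB3, a pseudokinase gene induced by stress, had a log2 difference of 1.35 (SE 0.64; 2.02 without WT replicate 1), an adjusted p of 0.264 and 3.23e-04 with the block. The chaperone genes PDIA4 and CRELD2 had log2 differences of 0.67 and 0.69, adjusted p-values (limma) of 0.0543 and 0.156, and 2.14e-04 and 0.00401 with the block. TRIB3 and CEBPB lie on chromosome 20 and PDIA4 on chromosome 7. Camera gave adjusted p-values of 0.271 for the ribosome list and 0.271 for the stress list without the block. With the block these were 7.07e-04 and 7.63e-04 at the preset correlation, and adjusted p = 0.8596 and 0.8596 with an estimated correlation. Without WT replicate 1 the unblocked values were 0.000204 and 0.000507 (adjusted p, camera). That fit keeps KO-labelled replicate 1 without its WT counterpart, so the replicate 1 difference given next adds to that of the genotypes. Mean deviations of ribosome list members from their means over libraries were -0.757, 0.712 and 0.447 in WT replicates 1 to 3. They were -0.865, 0.385 and 0.079 in the KO-labelled replicates. Replicate 1 of both genotypes differed from replicates 2 and 3 in the same lists, with a median log2 difference of -1.22 for the ribosome list and 1.13 for the stress list. Camera gave both an adjusted p = 0.742 in that comparison with an estimated correlation, a version with little power here.

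The neighbours of TNK2 on 3q29 did not pass the test as a group. Of 32 genes tested 1 rose, 1 fell and 30 did not pass, with a median log2 difference of -0.05 and 5 up and 6 down with the block. TM4SF19, which has a read-through transcript with its neighbour and is therefore uncertain, rose from 3.31 to 203, and NRROS fell 2.73-fold. Their adjusted p-values (limma) were 0.00102 and 0.0149, the latter 0.0731 without WT replicate 3. MUC4 and PAK2 had adjusted p-values of 0.165 and 0.188, and 6.29e-04 and 0.00213 with the block (limma). The camera adjusted p was 0.941.

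Markers of other cell types and of RNA quality were read last. Epithelial and fibroblast markers had 3 rises, 2 falls and 5 that did not pass among 10, with 5 up and 2 down with the block. The keratin genes KRT19 and KRT8 rose 11.3-fold and 2.29-fold, to 2565 ± 449.6 and 12066 ± 2775 (SD, n = 3 each), and COL1A1, chosen after its values were seen, rose from 16.3 to 133 (log2 3.20, and 2.58 and 3.85 without WT replicates 2 and 3). The mesenchymal transcription factor gene TWIST1 fell 34.3-fold although it lies on chromosome 7, and FN1, the fibronectin gene, 2.03-fold. Adjusted over all tested genes, limma p-values were 0.00104, 0.0127, 0.0334, 8.11e-05 and 0.0209, and without KO-labelled replicate 3 0.0593 for KRT8, 0.123 for COL1A1 and 0.0809 for FN1. KRT18, abundant in both groups, had means of 8685 ± 2619 and 10034 ± 2018, an adjusted p of 0.674 and 0.0468 with the block. In WT cells KRT8 and KRT18 were at 5179 and 8685, so K562 itself expresses them. Of 7 lymphoid markers PRF1, the perforin gene, fell 4.55-fold (adjusted p 0.0401, and 0.156 without WT replicate 3, limma) and 6 did not pass. The abundant members CD3D and CD3G had adjusted p-values (limma) of 0.724 and 0.788, and CD3E and TRBC1 had 0.336 and 0.151, the last 0.0256 with the block and on chromosome 7. None of 13 mitochondrially encoded mRNAs passed limma, none had an unadjusted p under 0.05 and none passed with voom weights or without the variance trend, with 2 falls with the block; MT-CO1 and MT-ND4, the most abundant, had log2 differences of 0.01 (SE 0.23) and -0.10 (SE 0.20). MT-ND6, MT-ND1, MT-ND2 and MT-ND4L had adjusted p-values (limma) of 0.368, 0.399, 0.296 and 0.531, with 0.00254 and 0.00213 for MT-ND6 and MT-ND1 with the block. These 13 genes took 6.54% to 7.82% of each library. Of 18 replication-dependent histone genes none passed, 1 had an unadjusted p under 0.05 and none passed with voom weights or without the variance trend, with 2 falls with the block. H2BC12 and H1-2, the most abundant, had adjusted p-values (limma) of 0.601 and 0.889, and H2AC6, H2BC9, H3C10 and H1-5 had 0.263, 0.196, 0.576 and 0.3502, with 0.00547 and 0.00484 for H2AC6 and H2BC9 with the block. Of 20 heat shock and dissociation stress genes none passed, none had an unadjusted p under 0.05 and none passed with voom weights or without the variance trend, with 5 up and 5 down with the block. HSPA8 and HSP90AA1, the most abundant, had adjusted p-values (limma) of 0.618 and 0.808, with 0.001604 for HSPA8 with the block, and HSPA1A, HSPA1B, DNAJB1 and DUSP1 had 0.272, 0.368, 0.236 and 0.2599, with 0.0146 for DUSP1 with the block. HSP90AA1 lies in the chromosome 14 segment of CDC42BPB and DUSP1 on chromosome 5. HSPA1A and HSPA1B are near-identical copies, and their values are uncertain. Camera gave adjusted p-values of 0.628, 0.734, 0.271, 0.551 and 0.734 for the epithelial, lymphoid, mitochondrial, histone and heat shock lists.

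**Figure D5:**
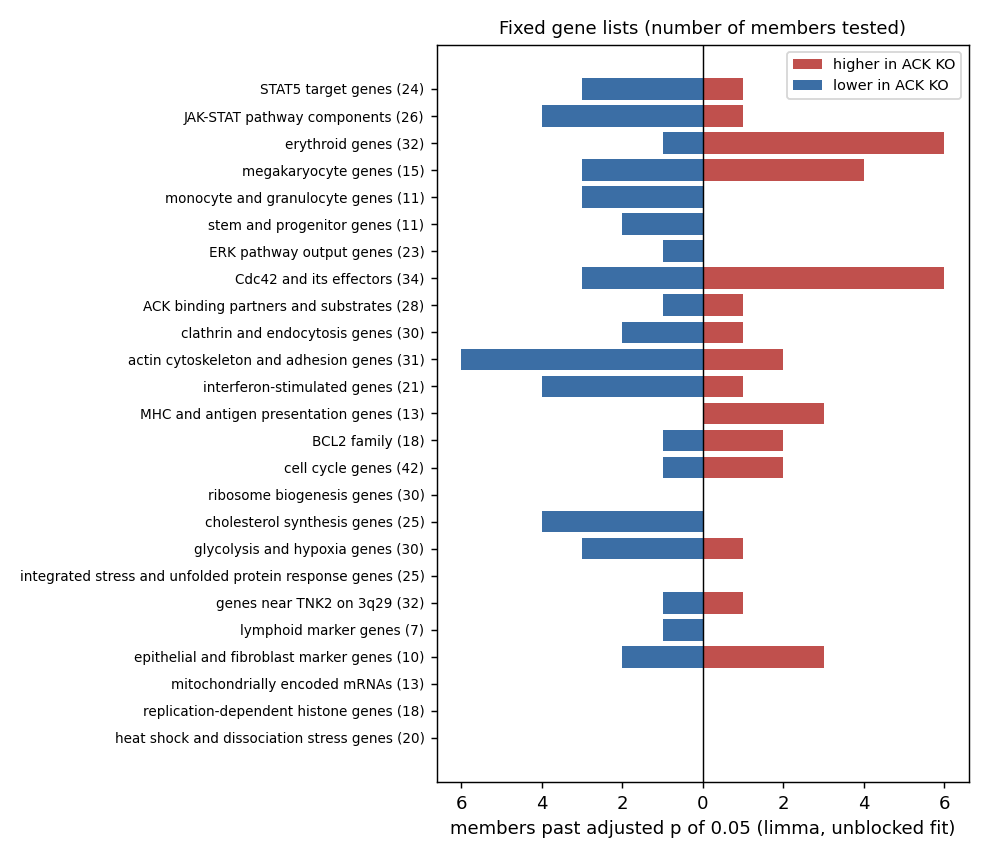
Number of members of each of the 25 lists past an adjusted p of 0.05 in the limma fit without the block, higher in KO-labelled libraries to the right and lower to the left, with the number of members tested in parentheses. The erythroid and Cdc42 lists have the most rises (6 each) and the actin and adhesion list the most falls (6).

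None of the 25 lists passed camera in the fit of all 6 libraries without the block. The lowest adjusted p was 0.271, and fry, a rotation test of each list on its own, passed none either. With the block camera passed the ribosome biogenesis and stress lists at the preset correlation, with adjusted p = 0.8596 for both with an estimated correlation. Many other lists had this same value, so the version with an estimated correlation decides nothing about these. With the block fry gave the interferon-stimulated list an adjusted p of 0.0208, where camera gave 0.306, and adjusted p = 0.8596 with an estimated correlation. The median, mean and camera direction of a list differed in sign for 5 lists. These were the megakaryocyte list (median -0.10, mean -0.12, camera up), the ERK list (0.03, -0.16, down), the MHC list (-0.36, 0.06, up), the 3q29 list (-0.05, 0.13, down) and the lymphoid list (0.06, -0.18, down).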

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

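The fit on replicates 2 and 3 was chosen after the data were seen, and all other alternatives were set before. Count-based tests planned in case the values were whole reads were not run. The count of 1721 changed genes was 6612 with the block, 4731 on replicates 2 and 3 and 726 to 2183 without 1 library, and the count of 1217 genes at least 2-fold was 2164, 1899 and 696 to 1494. The other settings gave 1385 to 1936 and 868 to 1344. Fewer libraries were tested in the leave-one-out fits, which does not account for the 2183 genes without WT replicate 1. The cause of the shifts was not tested. TNK2 did not pass in any setting, with log2 differences from -0.32 to -0.05 and adjusted p-values from 0.207 to 0.929 (limma).

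For the 91 named genes past the threshold, 1265 of 1448 results under the alternatives kept direction and side, 183 lost significance and none turned direction. The calls of 51 held without each library in turn and those of 40 were lost without at least 1. These fits without 1 library used no block, and all 91 genes passed with the block on all 6 libraries. For the 48 named genes not past it, 683 of 765 results stayed, 65 passed and 17 turned direction. Log2 differences that turned were 0.00436 for MT-ND4L with quantile normalisation and, on replicates 2 and 3, 0.0206 for MT-ND4, 0.12 for HSP90AA1, -0.12 for MT-CO1 and 0.23 for CISH. Without 1 library the ranges were -0.0318 to 0.42 (KRT18), -0.31 to 0.83 (CD3G), -0.20 to 0.84 (CD3D), -0.17 to 0.0128 (MT-ND4), -0.27 to 0.10 (H1-2), -0.13 to 0.12 (MT-CO1), -0.23 to 0.13 (CISH), -0.49 to 0.00669 (H2BC12) and -0.53 to 0.27 (HSP90AA1). The cause was not tested.

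Of 450 list results 6 passed, those of the ribosome and stress lists with the block (0.000707 and 0.000763), without WT replicate 1 (0.000204 and 0.000507) and on replicates 2 and 3 (0.000247 and 2.56e-05, adjusted p of camera), and 18 differed in direction. With the block and an estimated correlation, which has little power here, both lists had an adjusted p (camera) of 0.8596. The fit without WT replicate 1 keeps KO-labelled replicate 1, so the replicate 1 difference adds to that of the genotypes. Adjusted p-values of lists that turned were, for 3q29, 0.883 without the filter, 0.993 with quantile normalisation, 0.603 with fry, 0.944 on replicates 2 and 3 and 0.889 to 0.955 without 1 library. They were 0.831 with a mean of 50 and 0.702 to 0.933 without 1 library for the megakaryocyte list, 0.751 with the block, 0.782 on replicates 2 and 3 and 0.679 to 0.994 for MHC, and 0.781 on replicates 2 and 3 and 0.141 to 0.834 for cholesterol. The epithelial list had 0.555 with fry. Without 1 library the lymphoid list had 0.485 to 0.906, the ribosome list 0.000204 to 0.925 and the heat shock list 0.453 to 0.906. The cause was not tested. Depth is unknown, so what it limits could not be measured.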

Other observations

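Tests chosen after the result was seen are those of a line that is not erythroid, of separate lines or clones, of a single odd library, of genes changed at least 8-fold, of chance order, copy number and the replicate 1 difference for the chromosome shifts, of the replicate 1 difference for the number of genes and within the stress and ribosome lists, and of list members on other chromosomes. Those on splits of the samples, the share of genes in shifted windows, 3q29, unspliced reads and the stress and ribosome lists together were written before.

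SNHG14, SNRPN and SNURF, transcripts of the imprinted region 15q11, were chosen after their values were seen. SNHG14, a long non-coding host transcript of small nucleolar RNAs, rose from 12.02 ± 2.48 to 2488 ± 183 (SD, n = 3 each), a log2 difference of 7.59 with a standard error of 0.23 and an adjusted p of 3.78e-05 (limma). SNRPN and SNURF, which share exons so that their reads cannot be told apart, were listed at 0 in WT and had means of 975 ± 71.3 and 34.8 ± 11.4.

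Replicate 1 of both genotypes, compared with replicates 2 and 3 after it was seen to stand apart, had 3650 genes higher and 3905 lower (limma, Benjamini-Hochberg). Ribosome biogenesis genes were lower in 30 of 30 members and 19 stress response genes were higher against 3 lower, with camera adjusted p-values of 2.46e-16 and 9.86e-07. The cell cycle list (2 higher and 27 lower of 42), the monocyte and granulocyte list (7 higher and 0 lower of 11) and the cholesterol list (1 higher and 13 lower of 25) also passed camera, at 7.46e-06, 0.00138 and 0.00196, as did the MHC list (7 higher and 2 lower) at 0.0295 and the glycolysis list (4 higher and 12 lower) at 0.0405. With an estimated correlation none of the 7 passed, with adjusted p = 0.742 to 0.889. That version gave 0.742 to the ribosome list too, with 30 of 30 members lower, and has little power here. Members that move together can also make the p-values at the preset correlation too small. The genes that follow were chosen after their values were seen. INHBE and TRIB3, targets of the integrated stress response, were higher by a log2 of 2.95 and 1.71, and NOP16 and UTP20, which act in ribosome assembly, had log2 differences of -1.90 and -2.06.

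The first pattern is that neighbouring genes shifted together, down along nearly all of chromosome 5 and up along chromosome 20 and in 8 segments of chromosome 7 with 645 of its 834 tested genes, as well as in 13 segments of other chromosomes. Shifted windows hold 16.2% of tested genes, against 0.824% at most in shuffled orders, which argues against chance order. In the comparison of replicate 1 with replicates 2 and 3 such windows hold 9.25%. Orders were not shuffled for that comparison, so whether neighbouring genes shift together there is not known. Whether the same windows shift in that comparison was not tested. That comparison gave chromosomes 5, 7 and 20 medians no farther from 0 than -0.0929. In the genotype contrast the 3q29 neighbours of TNK2 had a median of -0.0509. A candidate explanation is a difference in DNA copy number between the 2 lines, which stays a hypothesis: DNA was not measured here, 34.1% of the called genes lie in shifted windows, and 18 of 18 medians with the sign of their chromosome follow from how the chromosomes were picked. Regions of 100 or more genes reached a median of 0.664 in size, short of the changes of at least 8-fold, and loss or gain of single genes or small segments was not tested.

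The second pattern is the number of changed genes, 1721 for the real split, where 1 of 10 splits gave as many and the highest other gave 1 gene; 10 splits are too few for a share under 0.05. Among the splits that part the replicate pairs, the block gave 6612 genes for the real one and 0 for the other 3. Each split other than the real one mixes both labels in each group, so the genotype difference widens its spread. Low counts there were fixed in advance and do not measure chance. A line without the erythroid programme behind the KO-labelled libraries is argued against by the erythroid list, with a median log2 difference of 0.157. If a difference of the kind that sets replicate 1 apart made up most of the genotype contrast, the 2 would resemble each other. The 4 correlations across genes were only 0.0618 to 0.0895. A smaller share of such a difference is not excluded, since genes with large genotype differences can dilute these correlations. Loss of ACK, another erythroid line and a difference between K562 sublines or clones stay open beside the chromosome shifts and the 39 and 50 genes with a mean of 100 or more under 1 label and under 10 in each library of the other, since 0 genotypes have more than 1 labelled line.

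The third pattern is that the stress list rose and the ribosome list fell with the block at the preset correlation. These are the directions they have in replicate 1. With an estimated correlation the adjusted p (camera) was 0.8596 for both lists, and 0.742 for both in the replicate 1 comparison. That version has too few degrees of freedom here to decide. For replicate 1 itself a single odd library is argued against by a correlation of 0.699 between the genotypes. That is the value that paired the replicate numbers, and not a separate test. For unspliced template, sense-intronic and antisense genes together (1173 genes) had an excess of -0.328 in KO-labelled and -0.309 in WT replicate 1. In stranded libraries unspliced RNA of a host gene adds nothing to antisense genes, so this pooled value cannot decide. In replicate 1, genes without signal were fewer (206 in WT and 178 in KO-labelled, against 272 to 388 in the other libraries). The median of the lower-valued genes was higher (26.9 and 28.8, against 18.1 to 21.3). Read depth is unknown, so unspliced template stays open. What sets replicate 1 apart was not established. Within the stress list the genotype and replicate 1 contrasts correlated at 0.30 or more, so the same kind of difference between cultures, growth state for example, may contribute to it. Within the ribosome list the lowest correlation was -0.180, which decides nothing, and the value of 0.723 for both lists together is fixed by their opposite directions. Members on chromosomes other than 5, 7 and 20 still gave an unadjusted camera p of 0.00354 or lower with the block, and a response to the loss of ACK was not separated from such a difference.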
